A study of Caenorhabditis elegans with 2 samples.

How the data were processed

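Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed for CEC-7, a chromodomain protein of Caenorhabditis elegans encoded by Y37D8A.11, in adult hermaphrodites that carried the fem-2(b245) mutation and were kept at 20 °C. The labels differ on the stage. The stage entry gives young adults with a germ line, whereas the growth protocol describes gravid adults, and embryos inside gravid adults would add their chromatin to every value. The series held 1 ChIP library and 1 library of input DNA from the same strain and stage. Worms were frozen, ground and fixed with formaldehyde, the chromatin was sheared by sonication, and CEC-7 was precipitated with an affinity-purified rabbit polyclonal antibody, per the labels' protocols.

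The ChIP library came with 1 peak list, and no processed file of the input was used here. Peaks were called with MACS on the WormBase WS220 assembly, per the file headers and the source column of the list. Reads were aligned with BWA and the build was ce10, the name under which the UCSC browser carries WS220, per the submitters' processing notes. The versions of both tools, the read filters, the treatment of duplicate reads and whether the input served as the control are not given in the sources used here. The deposited list gave a start and an end (1-based) and a score for each peak. The score is the authors' peak caller's own value, and its unit was not stated per the file headers. Its lowest value was 50 and its highest 3100, which is the range of a transformed p-value with a cutoff. It was therefore used to rank, filter and describe peaks within the list, as values, medians, rank correlation and order, and no fold was formed from it. The peaks were numbered without a break from 1 to 4116. Read depth is unknown, because the list gave no counts, and no interval that needs depth is printed. With 1 ChIP library there is no biological or technical replicate. No p-value was computed, and every range given for a value describes this list and not the spread between worms or precipitations.

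The list held no chromosome lengths, so the end of the last peak on each chromosome was taken as that chromosome's extent. Peaks were assigned to chromosomes, by their midpoint to 3 equal segments of the extent (left, central and right, of which the left and right are called outer), and to windows of 1 Mb and 250 kb with covered bases split exactly. Chromosome shares were compared with 1000 draws in which the same number of peaks fell at random over the 6 extents. Shares of peaks in the outer segments and shares with a neighbour within 5 kb, edge to edge, were compared with 1000 random placements that kept the widths, the chromosome and the absence of overlap. The central 95% of the draws is given as the random range. Because these draws ignore clustering, ranges that keep it were added after seeing the data. For the segments, all peaks of a chromosome were shifted together by a random circular offset 1000 times. For chromosome shares, each chromosome was filled 1000 times with 1 Mb blocks drawn from all chromosomes. Intervals for densities, coverage, ratios of median widths and the order of scores were 95% block bootstrap intervals, in which 1 Mb blocks were resampled 1000 times. They describe the unevenness along the chromosomes. Scores of 2 sets of peaks were compared by the percent of pairs in which the peak of the first set had the higher score, where 50% means no difference. The relation of score and width was given as Spearman's rank correlation across peaks, which are not independent replicates. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

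The placement test and the bootstrap were tested on simulated lists with the real number and widths of peaks. Of 100 evenly placed lists, 7% fell outside the random range for the outer segments and 3% outside that for neighbours. Of 100 clustered lists with no preference, made by circular shifts, 54% fell outside the random range for the outer segments and 5% outside the range of shifts. Of 120 chromosome shares in lists of drawn blocks, 67.5% fell outside the random range and 3.33% outside the block range. The 5% and the 3.33% were largely fixed in advance, because these lists were made in the same way as the ranges. They do not show that the ranges suit the real list. When 70% of the outer peaks were kept in evenly placed lists, all of the 100 lists fell outside the random range, with a mean outer share of 58.3%, and of clustered lists treated in the same way 95% fell outside the range of shifts. A width ratio of 1.3 was measured as 1.30 on average over 50 lists. For the order of scores, a planted 61.1% was measured as 61.1% on average over 20 lists. In 95% of lists with no planted difference the interval held 50%. The lists for widths and scores were evenly placed, and apart from the planted difference their values did not vary by region. The bootstrap was therefore not tested on lists in which neighbouring peaks resemble one another.

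The measures, the segments, the random placements and the rule for named items were fixed before the data were examined. That rule took the 25 peaks with the highest score. The alternatives fixed at the same time were the 2058 peaks with the better score, merging of peaks within 1000 bp, counting bases in place of peaks, removal of the widest 5% of peaks, outer segments that each span 25% of the extent, and neighbour distances of 2 kb and 10 kb. Other alternatives, chosen after seeing the data, were removal of the first 250 kb of each chromosome, omission of each autosome in turn, restriction to peaks with no neighbour within 5 kb, merging of peaks within 1000 bp for the neighbour share, and full WS220 chromosome lengths, which were entered by hand from memory because the list lacked them and were not checked against a source. The comparisons of width and score between the central and outer segments, and of the density on V with that on X, were also added after seeing the data. The planned comparisons with gene starts, exons, introns, gene lists and GC content were not run. They need an annotation or sequence of WS220, while the gene table at hand described the later assembly WBcel235, and coordinates of different assemblies were not mixed. Peaks are therefore named by position and not by gene.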

Results

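The occupancy of CEC-7 was profiled by ChIP-seq in fem-2(b245) adults labelled as young and containing a germ line, although the growth protocol describes gravid adults. The fem-2 gene encodes a protein phosphatase that promotes male development. CEC-7 belongs to the chromodomain proteins, a group named for a domain that in several members binds methylated histone tails. A ChIP library and an input library were collected, and the result used here was the peak list of the ChIP library; whether the input entered the peak calls was not stated. The list contained 4116 peaks on all 6 nuclear chromosomes, with 4075 on the 5 autosomes and 41 on X. Together they covered 12.6 Mb, or 12.6% of the chromosome extents. The peaks were broad. Their median width was 2.29 kb, with quartiles of 1.53 and 3.90 kb, and 631 peaks (15.3%) were wider than 5 kb. The authors' score had a median of 196 and quartiles of 99.3 and 431. Wider peaks had higher scores, with a Spearman correlation of 0.82 across peaks. No replicate of the ChIP was analysed, and depth was not given in the list.

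CEC-7 peaks were nearly confined to the autosomes. The X chromosome, which is largely silent in the germ line of C. elegans, made up 17.4% of the summed chromosome extents and carried 1.00% of the peaks, against a random range of 16.2% to 18.5%. By length, 715 peaks would have fallen on X. Peak density was 2.37 per Mb on X (95% block bootstrap interval 0.81 to 4.93) and 49.5 per Mb on the autosomes, a ratio of 20.9 (interval 9.86 to 62.0). The share of bases inside a peak was 0.55% on X and 15.2% on the autosomes. Of the 17 full 1 Mb windows of X, 8 contained no peak midpoint, whereas each of the 80 full autosomal windows contained at least 1. Of the X peaks, 21 lay within the first 250 kb. Without the first 250 kb of each chromosome, the share of peaks on X was 0.50%.

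The autosomes also differed from one another. Chromosome III had the highest peak density, 70.8 per Mb (interval 64 to 79.3), followed by chromosome I with 66.7 per Mb (57.8 to 75.8). Chromosomes II and IV had 49.4 per Mb (40.2 to 58.3) and 45.4 per Mb (35.8 to 54.1). Chromosome V, the longest chromosome and one rich in chemoreceptor gene families, had 26.4 per Mb (21.8 to 30.5). Density on V, the autosome with the lowest value, was 11.1 times that on X (5.25 to 32.3). Coverage gave the same order, with 24.1% of chromosome III, 20.98% of I, 15.7% of II, 12.6% of IV and 6.87% of V inside a peak. The random range places peaks independently and is too narrow for clustered peaks, so shares were also compared with 1 Mb blocks drawn from all chromosomes. The peak shares of I and III exceeded both ranges, and those of V and X fell below both. Chromosome II, with 18.3% of the peaks, exceeded the random range of 14.2% to 16.3% but not the block range of 10.2% to 20.2%, and IV, with 19.3%, exceeded 16.4% to 18.7% but not 12.2% to 22.7%. The share of IV in the covered bases, 17.5%, lay inside the corresponding random range. Both kinds of range include X, so the scarcity of peaks on X raised every autosomal share against them. Compared with the density of all autosomes, 49.5 per Mb, II was alike and IV lower, and the intervals of both held that value. The intervals of I and III lay above it and that of V below. Coverage of IV, 12.6%, was also under the 15.2% of all autosomes.

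**Figure D1:**
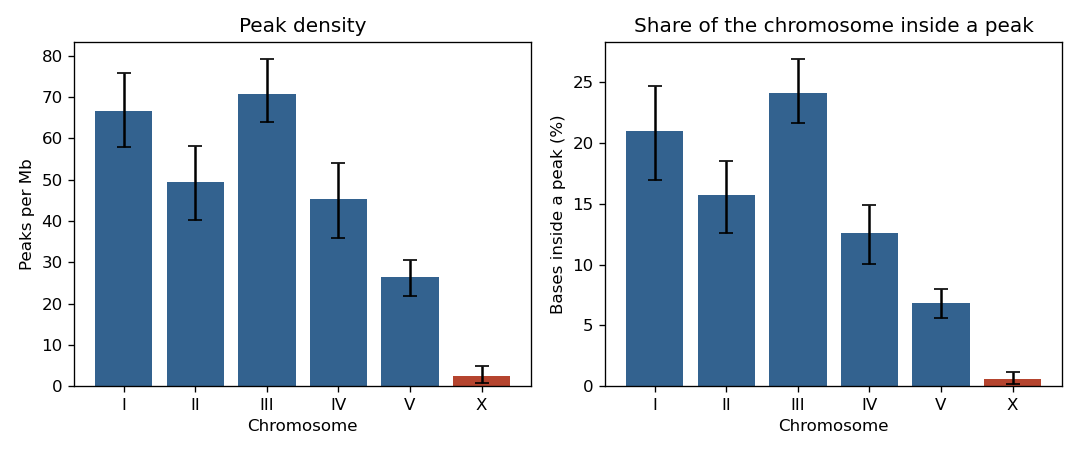
Peaks per Mb (left) and percent of bases inside a peak (right) for each chromosome of the 1 CEC-7 ChIP library. Bars give the value over the chromosome extent and error bars the 95% block bootstrap interval over 1 Mb blocks; X, at 2.37 peaks per Mb, lies far below chromosome V at 26.4.

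Within autosomes, the share of peaks in the outer segments, summed over chromosomes, did not leave its random range. Peaks in the central segments were broader. The arms of C. elegans autosomes are rich in repeats and in histone H3 lysine 9 methylation, and the centres hold many broadly expressed genes. Each chromosome was divided into 3 equal segments, of which the central one was compared with the outer ones. These segments did not follow arm boundaries, so their values are not values for the arms. The outer segments held 66.8% of the autosomal peaks, inside the random range of 65.4% to 67.8%. The median width was 3034 bp in the central segments (quartiles 1948 and 4958 bp, 1351 peaks) and 2016 bp in the outer segments (1427 and 3291 bp, 2724 peaks), a ratio of 1.505 (95% block bootstrap interval 1.38 to 1.65), above the range of 0.77 to 1.33 from random circular shifts, which keep the clustering of peaks. Of the central peaks 24.9% were wider than 5 kb, against 10.7% of the outer ones. Each of the 5 autosomes had the larger median width in the centre, with ratios from 1.37 on chromosome IV to 1.64 on chromosome I. The median score was 274 in the central and 172 in the outer segments, and a central peak had the higher score in 61.0% of central and outer pairs (interval 57.9% to 64%; range of shifts 42.2% to 57.7%), where 50% means no difference. By covered bases the distribution was uneven. The outer segments held 58.5% of the covered autosomal bases, below the random range of 65.2% to 68.1% and the range of shifts of 60.4% to 73.2%, and 18.9% of the central and 13.3% of the outer sequence lay inside a peak. The share of peaks in the outer segments depended on the peaks taken. It was 59.9% among the 2058 peaks with the better score, which follows the higher central scores, against a random range of 64.7% to 68.4% and a range of shifts of 60.4% to 73.7%. Without the widest 5% of peaks it was 68.2%, above the random range of 65.4% to 68.0% and inside the range of shifts of 61.5% to 71.3%.

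**Figure D2:**
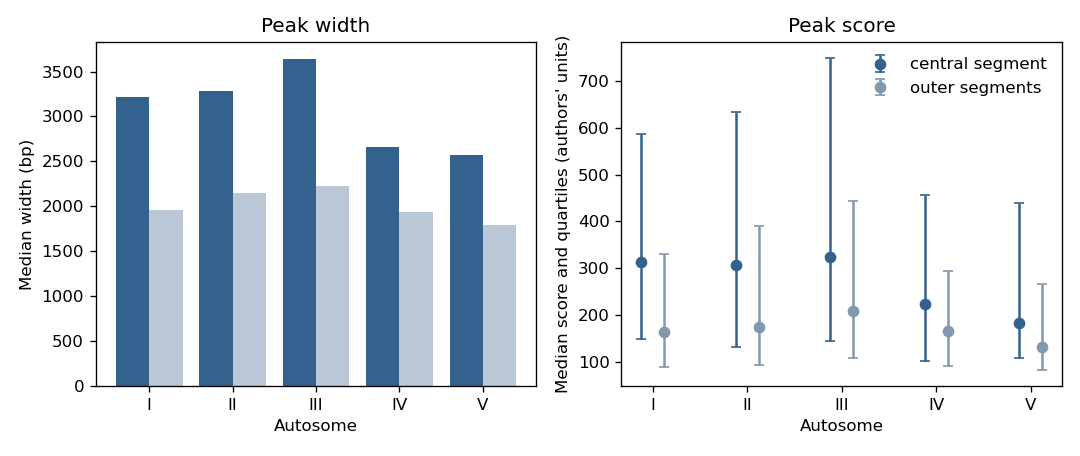
Median peak width in bp (left, bars) and median score in the authors' units (right, points, with lines from the lower to the upper quartile over peaks) in the central segment and in the outer segments of each autosome, from 1 library, so no replicate error is drawn. The central median is higher on each of the 5 autosomes for both measures; the dark marks are the central and the light marks the outer segments.

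The segments of a chromosome held unequal numbers of peaks when compared with independent random placement. On chromosome II the left segment held 159 peaks, under the random range of 228 to 273, and the right segment held 344, above its range. On chromosome I the left segment held 388 peaks and the right segment 264, against ranges of about 310 to 359 and 313 to 358. Chromosome IV had 320 peaks on the left and 206 on the right, with ranges of 241 to 286 and 243 to 289. Chromosome III had 375 peaks on the right, above its range of 303 to 349, 310 on the left, inside its range, and 289 in the centre, below its range of 301 to 348. The central counts of the other autosomes lay inside their ranges. The 3 segments of chromosome V, with 166, 192 and 192 peaks, all lay inside their ranges. These random ranges ignore clustering and are too narrow for clustered peaks. Against circular shifts, which keep the clustering, every segment of the autosomes lay inside its range except the right segment of I. That segment had 264 peaks, at the lower edge of 265 to 393. The shifts move the same peaks along the same chromosome, so their ranges span its own unevenness. Lying inside them was nearly assured and does not decide whether the differences between segments are real.

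The most heavily covered full 1 Mb window was III from 5 to 6 Mb, where 33.8% of the bases lay inside one of 60 peaks. It was followed by III from 8 to 9 Mb (32.6%), I from 6 to 7 Mb (30.9%) and I from 5 to 6 Mb (30.7%). Of the 23 autosomal windows with more than 20% coverage, 10 were on chromosome III, 8 on I, 3 on II, 2 on IV and 0 on V. The lowest autosomal windows were V from 2 to 3 Mb (1.83%), V from 3 to 4 Mb (2.16%) and II from 3 to 4 Mb (2.37%). The right arm of chromosome IV was low over several Mb, with 3.83%, 4.10% and 3.28% in the windows from 14 to 17 Mb. The longest stretch between neighbouring peaks was 5.29 Mb on X (X, 2064199 to 7351162). On the autosomes the longest was 0.59 Mb on V (15766877 to 16359023), then 0.56 Mb on V (8615327 to 9176170) and 0.52 Mb on IV (15896625 to 16417970).

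**Figure D3:**
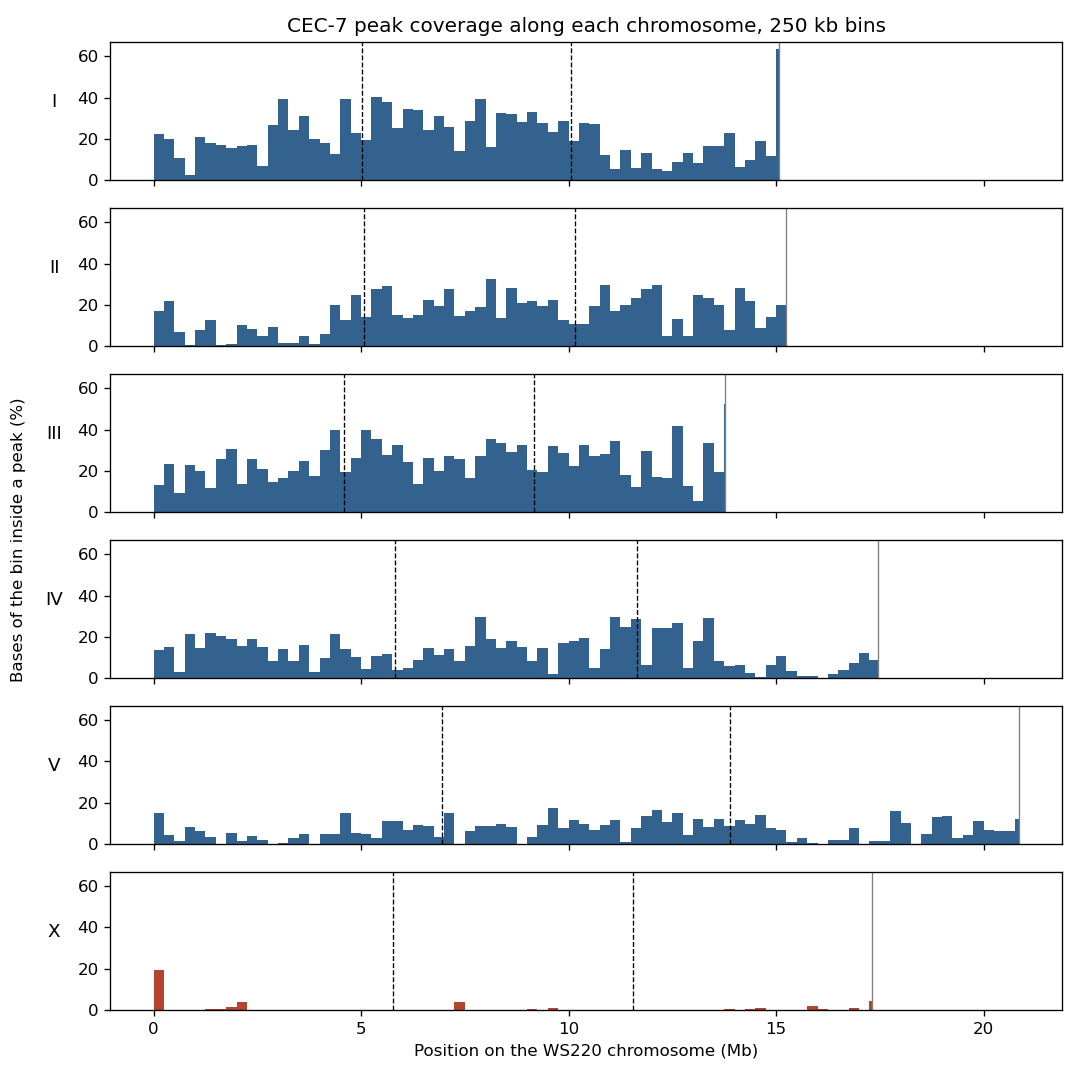
Percent of bases inside a CEC-7 peak in 250 kb bins along each WS220 chromosome, from 1 ChIP library. Dashed lines mark the segments and the grey line the end of the last peak, where the last bin is shorter than the others; coverage reaches X mainly in its first bin, at 19.3%, while chromosome IV drops beyond 14 Mb.

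Peaks occurred in clusters. Of all peaks, 82.9% had a neighbour within 5 kb, against a random range of 45.8% to 49.3%. The median distance between neighbouring peaks was 1914 bp on chromosome III, 2348 bp on I, 2386 bp on II, 2556 bp on IV, 7295 bp on V and 9481 bp on X, where 20 of the distances lay between the peaks of the left tip. Between the X peaks beyond the tip the median distance was 360 kb.

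The 25 peaks with the highest score were distributed as 10 on chromosome I, 8 on III, 3 on V, 2 on II, 1 on IV and 1 on X. Of the 24 autosomal ones, 16 lay in the central segment. Their median width was 8.43 kb, against 2.29 kb for the whole list. The highest score, 3100, belonged to a 5.85 kb peak on the right arm of chromosome I (13609699 to 13615552). The second, 3067, belonged to a 4.98 kb peak on the left arm of the same chromosome (1755195 to 1760177). Chromosome III had the third, a 9.69 kb peak at 5449620 to 5459312 with a score of 3013, and the twelfth, a 7.55 kb peak at 5460842 to 5468390 with a score of 2318, which began shortly after the end of the former. The fourth was an 8.83 kb peak on V (7916534 to 7925358, score 2894), the fifth a 7.21 kb peak on III (4991150 to 4998361, score 2738) and the sixth a 7.57 kb peak on III (3417069 to 3424634, score 2449). The highest on II was at 9334056 to 9341523 (score 2381) and the highest on IV at 4799661 to 4809788 (score 2379). The only X peak in this set lay at 16929508 to 16932399, was 2.89 kb wide and scored 2302. The widest peaks were not the highest. The widest of all, 19.5 kb on chromosome I (6736789 to 6756289), had a score of 89.5, below the median of the list.

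On X, 21 of the 41 peaks lay between the first base and position 206873. This left tip had 84 peaks per Mb over the first 250 kb and 19.3% of its bases inside a peak. In the first 250 kb of the autosomes, coverage ranged from 13.1% on III to 22.5% on I. Over the first 1 Mb of X, coverage was 4.83%, and 10 of the 80 full autosomal windows lay below that. The rest of X had 1.17 peaks per Mb and 0.27% coverage. Among 10000 random placements of the X peaks, no more than 5 fell within the first 250 kb, with a mean of 0.58. These draws place peaks independently, so they show that the X peaks cluster and not that the tip is special. The left segment of X held 26 peaks, above its random range of 8 to 20 but inside its range of circular shifts, 3 to 33. The tip peaks had a median width of 1893 bp and a median score of 168. The highest among them spanned 187507 to 190635 with a score of 1255. A stretch of 1.17 Mb without a peak followed. Beyond it, a peak at 2056610 to 2064198 was 7.59 kb wide with a score of 1063, and 4 peaks lay side by side between 7351163 and 7361447. The first 250 kb was chosen as a window after the positions had been seen.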

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

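Of the 81 alternative values computed, 69 kept their direction and their side of the random range or interval or, for the number of peaks and covered length, stayed within 1.5 times the value as deposited. The others follow. Leaving out an autosome, the comparisons of width and score, the hand-entered lengths and the removal of the first 250 kb were chosen after seeing the data, as were merging for clustering and the ranges that keep clustering. The number of peaks was 2058 at the stricter score, by construction, and 2735 after merging within 1000 bp. The share of autosomal peaks in the outer segments, which was inside its random range as deposited, went to 59.9% among the 2058 peaks with the better score and to 58.5% when bases were counted, both below their ranges. It was 65.2% after merging, inside its range on the other side of the random mean. Without the widest 5% of peaks it was 68.2%, above a range of 65.4% to 68.0%; wide peaks lie more often in the central segments. Leaving out each autosome in turn gave 65.8% to 67.5%, all inside the range, with the lowest value, on the other side of the random mean, without chromosome III. Chromosome IV held 18.1% of the 2058 peaks with the better score and 17.5% of the covered bases, both inside their ranges, the latter just below the random mean. Against 1 Mb blocks drawn from all chromosomes, the shares of II, 18.3%, and IV, 19.3%, lay inside the range. These chromosome ranges include X, which is poor in peaks, so they do not compare II or IV with the other autosomes. Against circular shifts, the outer share of all peaks stayed inside and the widths and scores above their ranges. The correlation of score and width was 0.83 without the widest 5% and 0.82 for all peaks. It was counted as changed because it lay just outside an interval of 0.81 to 0.83 around the latter. That interval treats peaks as independent, which they are not, so the change is not beyond their spread. The low share of peaks on X stayed below its random range under all 7 alternatives, from 0.50% to 1.21%, and the ratio of median widths stayed above 1 under all of those run, from 1.29 to 1.56. The percent of pairs in which the central peak had the higher score ranged from 59.4% to 62.1%. The share of peaks with a neighbour stayed above its random range in the better-scored peaks, at 2 kb, at 10 kb and after merging within 1000 bp, where it was 63.0% against 32.5% to 36.7%. The alternatives planned for gene starts, exons and introns, gene lists and GC content were not run, for want of a WS220 annotation. No paired analysis was possible because there was 1 ChIP library. The list holds only peaks past the authors' cutoff, so occupancy weaker than that, on X or elsewhere, was not detectable.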

Other observations

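The tests of the explanations for X and its left tip were chosen after the result was seen, as was the comparison of scores within widths; those for the widths were set before their values were computed.

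By number of peaks, left chromosome ends resembled one another more than their chromosomes did. The window was chosen after the X peaks in it had been seen, so the likeness of X was partly built in. The layout within the window differed. The first peak began at base 1 on I and X, and between positions 44134 and 119257 on the other chromosomes. The first 250 kb held 18 peaks on chromosome I, 17 on II, 14 on III, 14 on IV, 16 on V and 21 on X, although the rest of those chromosomes ranged from 71.0 peaks per Mb on III to 1.17 on X. On V the first 250 kb had 64 peaks per Mb against 25.9 over the rest. Right ends, taken as the last 250 kb before the end of the last peak, were less alike, with 8 peaks on I, 24 on II, 14 on III, 7 on IV, 6 on V and 1 on X. The last peak itself sets this window, so each holds at least 1. With WS220 lengths entered from memory, X had 0.

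The first pattern is the scarcity of peaks on X. An evenly lower sensitivity along X would have lowered its left tip as well. The tip had 84 peaks per Mb, above the autosomal 49.5. That window was chosen after its peaks had been seen, and a locally strong region could still pass the cutoff. The value shows that X was not poor in peaks throughout, but it does not decide on sensitivity. Reads that map less well over the rest of X, or a different scaling of ChIP to input there, were not tested, since neither read depth nor input signal was analysed here. A biological candidate explanation is that CEC-7 occupies chromatin of genes active in the germ line, which are scarce on X. It was not tested, as no gene could be placed on this assembly.

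The second pattern is the cluster of 21 peaks at the left tip of X, which remained 17 pieces after merging within 1000 bp. For a feature of both chromosome ends, the last 250 kb before the end of the last X peak held 1 peak, against 6 to 24 on autosomes. X is poor in peaks beyond its tip, so this count alone does not decide. With WS220 lengths entered from memory, the last 250 kb was denser than the rest on II (84 against 48.7 peaks per Mb). On I, III, IV and V it was sparser, so no excess shared by right ends was seen. A feature of left chromosome ends remains open, since 4 of the 5 autosomes were denser in the first 250 kb than over the rest. Among these the excess was largest on V, at 64 against 25.9 peaks per Mb. The densities were 68 against 49.1 on II, 56 against 45.3 on IV and 72 against 66.6 on I. On III the first 250 kb was sparser, at 56 against 71.0. As background, MES-4, a histone methyltransferase of the germ line, has been described on the autosomes and at the left tip of X, and overlap with it was not tested.

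The third pattern is the greater width of peaks in autosome centres. If domains in the outer segments split by gaps of up to 1000 bp were the only source, merging would have ended the difference. The ratio of medians after merging over that distance was still 1.44 (95% block bootstrap interval 1.24 to 1.62, range of circular shifts 0.744 to 1.3005). As deposited it was 1.505. A part played by such gaps, or splitting by longer ones, was not excluded. Joining of neighbours by the peak caller in dense regions stays open. Among 684 autosomal peaks with no neighbour within 5 kb the ratio was also 1.44 (1.25 to 1.67), but a joined cluster can itself stand isolated in the final list, so the bound set for that test did not separate the explanations. Longer or more closely packed occupied genes in the centres are a candidate explanation that was not tested.

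The higher scores in autosome centres were not seen at matched width. Within quartiles of width, from the narrowest to the widest, the central peak had the higher score in 46.0% (95% block bootstrap interval 40.6% to 51.0%), 42.9% (37.9% to 47.7%), 45.0% (40.9% to 49.0%) and 52.6% (48.3% to 57.4%) of pairs, against 61.0% over all autosomal peaks. The intervals of the second and the third quartile lay below 50%. Of the 4 values, only the 42.9% of the second quartile lay below its range of circular shifts, 43.8% to 55.0%. Its interval overlapped that range.

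The X peak at 16929508 to 16932399 ranked 13 by score and 1560 by width in the list, and its nearest neighbour lay 377 kb away. Among 388 other peaks within 10% of its width the median score was 295 and the highest 1555, against 2302 for this peak. Of the 10 widest peaks, 8 had scores below 500, and the widest, 19.5 kb on I, ranked 3241 by score.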
